A study of Mus musculus with 2 samples.

How the data were processed

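Gene expression and spatial barcodes were measured with 10x Genomics droplets in immune cells sorted from a B78ChOVA melanoma at 16 days, as 2 samples that were libraries of the same cells. Per the labels, 50 µl of tumour cells were injected, tumours were sectioned live at about 160 µm, and reads were processed with Cell Ranger 4.0.0 on mm10; the aligner settings are not given in the sources used here. The authors' deposited matrix held unfiltered UMI counts of both libraries, with the features of each kind named per the file headers, and the values were checked to be whole numbers. It held 117528298 gene UMIs and 14355102 spatial barcode UMIs over all barcodes, and 4592 barcodes with at least 500 gene UMIs and 4476 with at least 1000.

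Cells were kept with at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs, which gave 4236 cells with a median of 23132 gene UMIs and a median of 1552.5 spatial UMIs. Scrublet, as implemented in scanpy, was run on the kept cells, and its automatic threshold called 0 doublets, so none was removed. The profile of free RNA was the sum of 68497 barcodes with 10 to 100 UMIs. Counts were scaled to 10000 per cell, log transformed, reduced to 2000 variable genes less 123 state-list genes among them, scaled to at most 10, and clustered on 30 principal components and 15 neighbours with Leiden at resolution 1, 2 iterations and seed 0, which gave 22 clusters from 1877 genes. Genes of the cell cycle outside the state lists stayed among the clustering genes. A cluster took the name of the leading of 24 marker lists if at least 3 of its markers were found in 5% of its cells, and a cluster with T cell receptor complex and C1q genes each at 10% or more of the level in the cluster that holds the most was called mixed, a rule set after the data were examined. Classes carry the ending -like, since they rest on marker genes alone.

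Levels are CPM of counts summed over a set of cells with exact Poisson intervals, shares carry exact Clopper-Pearson intervals and ratios exact conditional binomial intervals, all at 95%. With 1 library these cover counting error only and not the differences between tumours, so no test was made and no gene was counted as changed. A gene was compared with at least 30 UMIs over both sets and, by a rule added after the data were examined, 3 UMIs expected in the smaller set at equal rates, and a set with 0 counts was put at a floor of 3 counts over the set. Lists with 19 gene states were written before the data were examined, and each median ratio was placed among 10000 random lists drawn within 50 ranks of expression of each member; this place describes the library and is no p-value. Ranges of medians come from 1000 Poisson redraws. Genes named are the 2 highest and 2 lowest of each list, and for splits and regions also the 10 highest and 10 lowest of all genes with at least 100 UMIs and 10% of cells in the higher set, save where a gene is said to have been chosen after its values were seen; in the paragraphs on secreted factors, levels of list genes per class were chosen that way. The results of 3 genes that met this rule are not reported here. Cxcl11 was missing from the features, so the chemokine list held 5 genes.

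The comparisons set before the data were examined were the class shares, macrophage-like against monocyte-like cells, CD8 T-like cells split by Pdcd1 and Havcr2, macrophage-like cells split by Mrc1, and classes by spatial barcode. Splits used cells thinned to 1000 UMIs, and levels were then taken from all UMIs. A cell took the spatial barcode with at least 10 counts and 2 times the next. The relative assignment divided each share by that of the same barcode in barcodes with 10 to 100 gene UMIs, needed 30 spatial UMIs and 1.5 times the next, and was added later, as were the comparisons of CD8 T-like clusters, monocyte-like cells and macrophage-like clusters 1, 2, 3, 6 and 9 and the omission of clusters 3 and 15 and of cells with CD3 or Cd4 UMIs. Sets with fewer than 20 cells for a barcode were not compared. Alternatives changed the UMI, gene and mitochondrial limits, the Leiden resolution, 4000 variable genes, seed 1, the state genes in clustering, the thinning, the averaging of cells, subtraction of free RNA and the barcode rule. The code was tested on simulated data with 200 changed genes: intervals held the simulated ratio for 95.6%, 96.0% and 97.3% of genes in macrophage-like against monocyte-like cells, in the CD8 T-like clusters and in CD8 T-like ZC1 against ZC3, and a ratio past 1.5 was reached by 98%, 84% and 90% of genes raised 2-fold. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9. Raw reads were not used here.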

Results

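Immune cells were sorted from live sections, about 160 µm thick, of B78ChOVA melanoma, a mouse tumour grown from injected cells, 16 days after injection under the skin. ZipSeq uses light to place DNA barcodes on the cells of chosen regions of a section before the tissue is dissociated, so that each droplet holds a cell's mRNA together with the barcode of its region. The 2 samples were the gene expression library and the spatial barcode (ADT) library of the same cells, counted in 1 matrix, with no replicates. The sample titles name a melanoma in the singular, but no count of tumours is stated. The region behind each of the spatial barcodes ZC1, ZC2 and ZC3 is not stated either. The matrix held 117528298 gene UMIs and 14355102 spatial barcode UMIs, of which 2200732 were ZC1, 3888790 ZC2 and 8265580 ZC3. After filtering, 4236 cells remained, with 1027 to 215512 UMIs per cell, a median of 23132 UMIs, 4320 genes and 3.65% mitochondrial UMIs. Levels are given as CPM, the counts summed over a set of cells and scaled to 1000000. Ratios are first set over second set, and intervals in parentheses are 95% intervals that cover counting error only.

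Macrophage-like cells, which carried the complement genes C1qa, C1qb and C1qc, were the largest class, with 2234 cells, 52.7% (51.2–54.3) in clusters 1, 2, 3, 6, 9, 10 and 15. Monocyte-like cells, marked by Ly6c2 and Ccr2, numbered 797 cells, 18.8% (17.6–20.02) in clusters 4 and 5. CD8 T-like cells, marked by Cd8a, Cd8b1 and the CD3 genes, numbered 367 cells, 8.66% (7.83–9.55) in clusters 7 and 12. The smaller classes were 144 cDC2-like, 103 Treg-like, 75 NK-like, 63 melanoma-like, 46 cDC1-like, 43 migratory DC-like, 39 nonclassical monocyte-like, 17 B-like and 14 pDC-like cells. Another 48 cells of a shallow cluster stayed unnamed. Cluster 8 held 246 cells, 5.81% (5.12–6.55), with both CD3 and C1q genes and was kept out of every class. Its CD3 genes reached 704 CPM, against 3728 and 3628 CPM in the CD8 T-like clusters 7 and 12. Its C1q genes reached 11697 CPM, against 11632 to 20297 CPM across the macrophage-like clusters. Clusters 3 and 15 had a marker of another class and none of the macrophage markers among their 10 leading genes (Cd300e of nonclassical monocytes and Cd79b of B cells, and F13a1 of monocytes), so their name is less sure, macrophages are compared between spatial barcodes by cluster, and the comparisons with monocyte-like cells and by Mrc1 were repeated without these clusters.

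**Figure D1:**
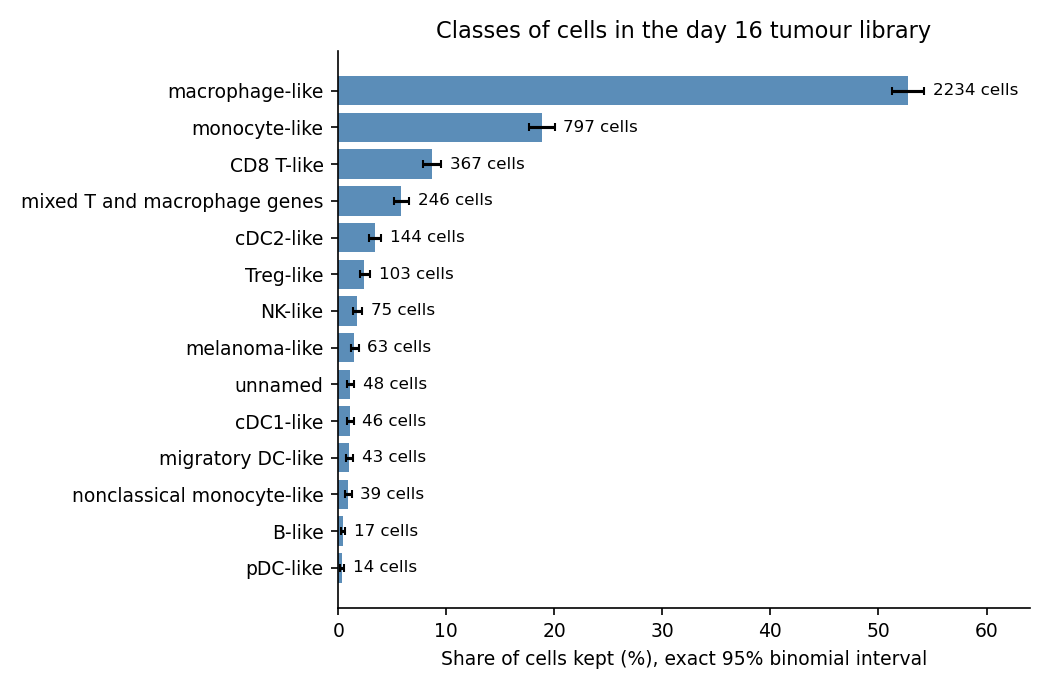
Share of the 4236 cells kept (x axis, percent) in each class (y axis), with bars for the share, lines for the exact 95% binomial interval and the number of cells beside each bar. Macrophage-like cells made up 52.7% and CD8 T-like cells 8.66%.

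**Figure D2:**
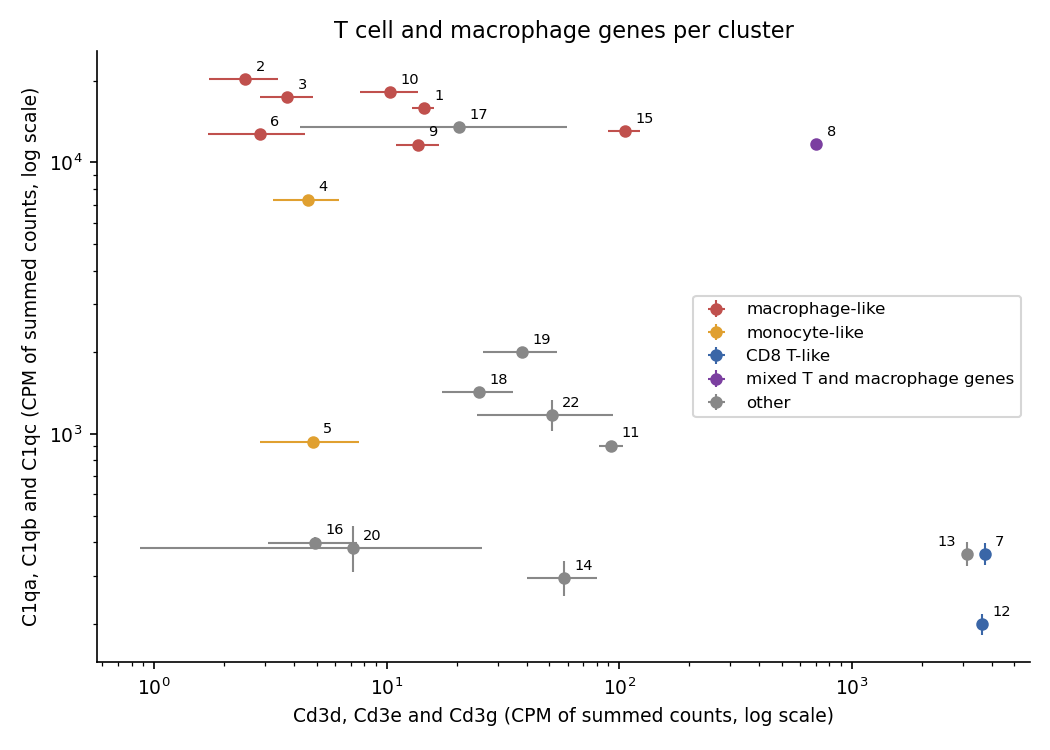
Summed counts of Cd3d, Cd3e and Cd3g (x axis, CPM, log scale) against C1qa, C1qb and C1qc (y axis, CPM, log scale), with a point per numbered cluster and lines for exact 95% Poisson intervals; the B-like cluster 21 had 0 CD3 UMIs and is not drawn. Cluster 8 sits at 704 CPM of CD3 genes and 11697 CPM of C1q genes.

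Macrophage-like cells were compared with monocyte-like cells to describe how the most abundant myeloid classes of the tumour differed. Proliferation genes were far higher in macrophage-like cells: the cell cycle list had a median ratio of 15.4 (percentile 100, 12 genes), the percentile being the list's place among 10000 random lists of matched expression. Ccnb1, the mitotic cyclin B1, stood at 62.1 against 2.04 CPM, ratio 30.5 (20.6–47.2), Birc5, which encodes survivin, at 210.3 against 9.45 CPM, ratio 22.2 (18.5–26.9), and the replication clamp gene Pcna at 152 against 60.4 CPM, ratio 2.52 (2.34–2.72). Ccnb1 stood at 167 CPM in cluster 1 and from 8.02 to 16.6 CPM in the other macrophage-like clusters. Ccl8, a chemokine of tissue macrophages, reached 1353 against 125 CPM, ratio 10.9 (10.3–11.4), and was chosen after its values were seen. Retnla, a gene of alternative activation, stood at 74.2 against 2.77 CPM, ratio 26.8 (19.2–38.7), but this came from clusters 9 and 15, 286 of the 2234 cells, at 645 and 781 CPM against 545 in free RNA. The other macrophage-like clusters lay between 1.07 and 2.63 CPM, not above monocyte-like cells. Lyve1, a hyaluronan receptor of resident macrophages, was at 2.24 CPM and had no UMI in monocyte-like cells, and cluster 15 held 161 of its UMIs. It was at least 9.18-fold higher at a floor of 3 counts over the set. Chil3, a chitinase-like gene of recruited monocytes, went the other way at 3.59 against 414 CPM, ratio 0.00868 (0.00764–0.00983), as did Spp1, osteopontin, at 140.5 against 477 CPM, ratio 0.294 (0.285–0.304). The inflammatory cytokine gene Il1b stood at 53.0 against 536 CPM, ratio 0.0989 (0.0951–0.103), and Ptgs2, the inducible cyclooxygenase, at 18.9 against 69.6 CPM, ratio 0.272 (0.2496–0.297). The monocyte chemokine gene Ccl2 was higher in macrophage-like cells at 1298 against 622 CPM, ratio 2.09 (2.04–2.14).

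Genes of lipid and lysosome handling had a median ratio of 1.42 (percentile 99.9, 10 genes). The cholesterol exporter Abca1 stood at 49.8 against 14.7 CPM, ratio 3.39 (2.92–3.96) and the protease gene Ctsd at 882 against 373 CPM, ratio 2.37 (2.30–2.44), with the fatty acid carrier Fabp5 lower at 0.667 (0.650–0.685). Glycolysis genes had a median of 1.42 (percentile 100, 11 genes), from 1.12 for hexokinase Hk2 to 1.70 for triose phosphate isomerase Tpi1. Type I interferon genes were lower in macrophage-like cells, at 0.358 (percentile 0, 10 genes), from 0.238 (0.216–0.262) for the antiviral GTPase gene Mx1 to 0.900 (0.700–1.17) for Ifi44. Interferon gamma response genes had a median of 0.630 (percentile 0.13, 8 genes), with the GTPase gene Gbp5 at 0.410 (0.370–0.454). Antigen presentation and costimulation were lower too, with MHC class II at 0.508 (percentile 0.0100, 9 genes), costimulatory ligands at 0.586 (percentile 1.72, 4 genes) and MHC class I at 0.806 (percentile 1.57, 10 genes). The dissociation stress list, a sign of handling, was lower as well, at 0.684 (percentile 0.2, 10 genes). Ciita, the regulator of class II genes, stood at 31.0 against 91.3 CPM, ratio 0.339 (0.316–0.365). The CD28 ligand genes Cd86 and Cd80 were at 0.423 (0.403–0.444) and 0.283 (0.223–0.359). The PD-1 ligand gene Cd274 was at 0.689 (0.647–0.735). Receptors for growth factors and chemokines had a median of 0.588 (percentile 0.0100, 11 genes), with the chemokine receptor gene Ccr1 at 0.325 (0.309–0.342). The chemokine genes Ccl4 and Ccl3 were higher in macrophage-like cells, at 1260 against 261 CPM, ratio 4.83 (4.67–5.01), and 395 against 119 CPM, ratio 3.32 (3.15–3.50). The class II difference rested on monocyte-like cluster 4, which also held C1q genes at 7305 CPM, and without this cluster the median log2 ratio went from -0.98 to 0.51. Alternative activation (1.16), inflammatory activation (1.42), hypoxia (1.15) and T cell attracting chemokines (1.05) had median ratios below 1.5 with members on both sides. With at least 500 UMIs and 250 genes per cell, the log2 medians of alternative and inflammatory activation turned to -0.77 and -1.47, and other settings also changed their sign, so no direction is given for these lists. Without macrophage-like clusters 3 and 15 the log2 medians of MHC class II and type I interferon genes were -0.86 and -1.35 instead of -0.98 and -1.48.

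**Figure D3:**
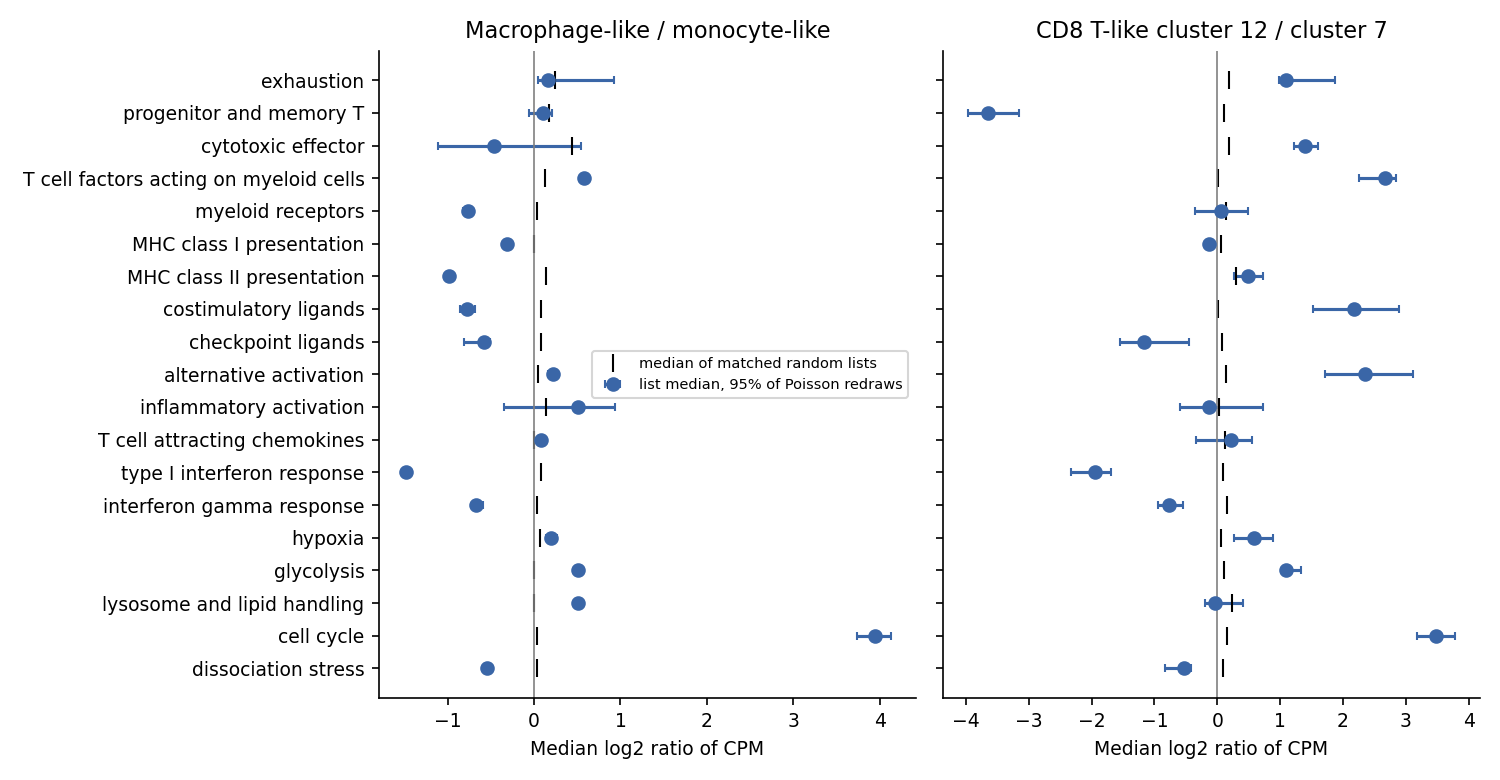
Median log2 ratio of CPM (x axis) for each gene list (y axis), macrophage-like over monocyte-like cells on the left and CD8 T-like cluster 12 over cluster 7 on the right, where points are list medians, lines the middle 95% of Poisson redraws and black ticks the median of matched random lists. The cell cycle list lies at 3.94 and 3.49, and the progenitor and memory T list at -3.65 on the right.

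The series title names exhausted CD8 T cells and macrophages, so secreted factors and their receptors were measured in each class beside the level in barcodes with 10 to 100 UMIs, which hold free RNA. Xcl1, a chemokine that attracts cDC1, was at 780.5 (753–809) CPM in CD8 T-like cells and 3608 (3458–3762) CPM in NK-like cells, against 1.45 in macrophage-like cells and 54.3 CPM in free RNA. Ifng, whose product activates macrophages, was at 345 (327–364) CPM in CD8 T-like and 213 (178–253) CPM in NK-like cells, 0.564 CPM in macrophage-like cells and 11.98 in free RNA. Csf1, the macrophage growth factor gene, reached 25.2 (20.5–30.8) CPM in CD8 T-like and 37.8 (32.3–43.9) CPM in melanoma-like cells, but 2.12 CPM in macrophage-like and 3.42 in monocyte-like cells and 5.55 in free RNA. Its receptor gene Csf1r was at 384 (379–388) CPM in macrophage-like and 532 (519–545) CPM in monocyte-like cells and highest in the 39 nonclassical monocyte-like cells, at 955 (844–1077) CPM, with 9.37 CPM in CD8 T-like cells and 239 in free RNA. Ccl5 was at 4504 (4437–4572) CPM in CD8 T-like cells, 5574 (5413–5738) CPM in migratory DC-like, 226 CPM in macrophage-like cells and 625 in free RNA.

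In the other direction, Cxcl9, a ligand of the T cell receptor Cxcr3, was at 1644 (1635–1654) CPM in macrophage-like and 1577 (1555–1599.7) CPM in monocyte-like cells, with 1120.3 CPM in free RNA. Cxcl16 was at 627 CPM in macrophage-like, 595 in monocyte-like, 993 in migratory DC-like cells and 501 in free RNA. Its receptor gene Cxcr6 was at 411 (391–432) CPM in CD8 T-like, 0.441 CPM in macrophage-like cells and 17.2 in free RNA. The inhibitory receptor gene Pdcd1 was at 113 (103–124) CPM in CD8 T-like cells and 9.93 in free RNA. Its ligand gene Cd274 was at 68.4 CPM in macrophage-like, 99.2 in monocyte-like, 319 (282–361) CPM in migratory DC-like and 336 (272–412) CPM in nonclassical monocyte-like cells. Free RNA held 76.6 CPM, above the macrophage-like level. Ccl3 and Ccl4 were shared. Ccl3 was at 1035 CPM in CD8 T-like, 1077 in nonclassical monocyte-like and 395 in macrophage-like cells, and Ccl4 at 988, 1367 and 1260 CPM in the same classes, with 344 and 1165 CPM in free RNA. Tnf was at 225 CPM in nonclassical monocyte-like cells. It was higher in macrophage-like cells, at 109 CPM, than in CD8 T-like cells, at 31.2 CPM, which lies below the 69.8 CPM of free RNA. On the mm10 (GRCm38) assembly, Pdcd1 (ENSMUSG00000026285) lies on chromosome 1 from 94038305 to 94052553, Csf1 (ENSMUSG00000014599) on chromosome 3 from 107741048 to 107760469, Csf1r (ENSMUSG00000024621) on chromosome 18 from 61100598 to 61132149 and Mrc1 (ENSMUSG00000026712) on chromosome 2 from 14229392 to 14332057.

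The CD8 T-like clusters 12 and 7 were compared to describe how T cell state differed between them, and this comparison was added after the data were examined. Exhaustion genes had a median ratio of 2.13 (percentile 100, 13 genes) in the 119 cells of cluster 12 over the 248 of cluster 7. Tnfrsf9, the costimulatory receptor 4-1BB, stood at 414 against 46.3 CPM, ratio 8.93 (6.91–11.7), and Havcr2, the inhibitory receptor TIM-3, at 88.2 against 11.2 CPM, ratio 7.87 (4.67–14.3). The homing receptor gene Cxcr6 differed little at 1.29 (1.16–1.45) and Cd101 at 1.02 (0.470–2.34). Progenitor and memory genes were lower, at 0.0798 (percentile 0, 7 genes). S1pr1, which lets T cells leave tissue, stood at 6.79 against 114 CPM, ratio 0.0598 (0.0339–0.0989). The transcription factor gene Lef1 was at 0.263 (0.165–0.410) and the coreceptor gene Slamf6 at 0.420 (0.314–0.560). Cytotoxic genes had a median of 2.65 (percentile 100, 9 genes) with members in both directions. Granzyme Gzmc was at 116 against 2.24 CPM, ratio 51.8 (17.6–253), with 47.1% of its UMIs in cluster 12 from 1 cell, whereas granzyme Gzma was at 19.96 against 254 CPM, ratio 0.0786 (0.0572–0.106). Cell cycle genes had a median of 11.2 (percentile 100, 12 genes), led by the nucleotide synthesis gene Rrm2 at 135 against 6.72 CPM, ratio 20.1 (10.5–44.4). Glycolysis genes had a median of 2.15 (percentile 100, 11 genes), led by Tpi1 at 3.62 (3.15–4.18).

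Factors that act on myeloid cells were higher in cluster 12, with a median of 6.34 (percentile 100, 9 genes). Ccl1, a ligand of Ccr8, stood at 421 against 4.48 CPM, ratio 94.0 (43.1–257), with 37.2% of its cluster 12 UMIs from 1 cell. Csf2, which encodes GM-CSF, was at 55.1 against 0.747 CPM, ratio 73.7 (13.02–2933), with 79.0% from 1 cell. Xcl1, Ccl3 and Csf1, chosen after their values were seen, stood at 1104 against 174 CPM, ratio 6.34 (5.55–7.28), at 1554 against 63.5 CPM, ratio 24.5 (19.7–30.7), and at 36.7 against 3.74 CPM, ratio 9.83 (4.06–31.0). Ccl5 and Tnf were lower, at 2626 against 8019.8 CPM, ratio 0.327 (0.317–0.338), and 25.5 against 41.8 CPM, ratio 0.611 (0.420–0.890). Cd70, a costimulatory ligand, was at 71.0 against 3.74 CPM, ratio 19.0 (7.9995–59.3), and the list of costimulatory ligands had a median of 4.54 (percentile 99.9, 4 genes). Interferon genes were lower in cluster 12, with type I interferon genes at 0.259 (percentile 0, 8 genes), led by Ifit3 at 8.78 against 108 CPM, ratio 0.0811 (0.0493–0.127), and interferon gamma response genes at 0.585 (percentile 0.410, 8 genes). The interferon gamma receptor gene Ifngr1 was at 119 against 423 CPM, ratio 0.280 (0.243–0.323). The dissociation stress list, a sign of handling, was lower in cluster 12, at 0.692 (percentile 0.650, 10 genes). Among lists of mostly myeloid genes, alternative activation was higher, at 5.12 (percentile 99.97, 4 genes), and checkpoint ligands lower, at 0.445 (percentile 0.535, 5 genes). With free RNA subtracted these lists were at 5.49 and 0.443. Myeloid genes read in T cells include free RNA, and the clusters differed in depth, with a median of 15587 UMIs per cell in cluster 12 and 5162.5 in cluster 7.

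Splitting CD8 T-like cells by detection of Pdcd1 and Havcr2, markers of exhaustion, was meant to set exhausted cells against the rest at equal depth. With each cell thinned to 1000 UMIs, Pdcd1 was detected in 20 of 367 cells (5.45%) and Havcr2 in 11 (3.00%), against 32.4% and 24.3% without thinning, where the median depth was 6148 UMIs. In cells that should lack these genes, Pdcd1 was found in 0 of 797 monocyte-like cells after thinning, which allows a share of up to 0.462%, and in 0.376% without thinning at a median of 13246 UMIs. Havcr2 was found in 0 of 63 melanoma-like cells after thinning, which allows up to 5.69%, and in 6.35% without thinning at a median of 71218 UMIs. Only 2 cells had both genes after thinning and 338 had neither, so this split could not describe a state at this depth. Summed over the 2 cells Cxcr6 stood at 2365 against 379.9 CPM, ratio 6.22 (4.70–8.10), but Ccl1 and Xcl1 were found in only 1 of them, and 1 cell gave 90.3% of the Ccl3 and 85.4% of the Gzmb UMIs. Their medians, which rest largely on single cells, were 2.42 for exhaustion genes and 6.15 for factors acting on myeloid cells.

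With Pdcd1 alone, 20 cells (17 of cluster 12 and 3 of cluster 7) were set against 347, at median depths of 14101 and 6042 UMIs. Their exhaustion genes had a median of 1.47 (percentile 99.9, 11 genes), with Rgs16, a regulator of G protein signalling, at 389 against 83.6 CPM, ratio 4.66 (3.75–5.75), and Havcr2 at 147 against 53.4 CPM, ratio 2.75 (1.96–3.80). Progenitor genes had a median of 0.198 (percentile 0, 7 genes), with the transcription factor gene Tcf7 at 9.19 against 74.8 CPM, ratio 0.123 (0.0252–0.363), and the interleukin 7 receptor gene Il7r at 9.19 against 73.1 CPM, ratio 0.126 (0.0258–0.372). Factors acting on myeloid cells had a median of 2.98 (percentile 100, 9 genes), but much of it came from single cells. The top cell of each gene held 88.6% of the Csf2 UMIs, 63.0% of Xcl1, 50.97% of Ccl3, 56.8% of Ifng and 34.1% of Ccl1. Their ratios were 82.8, 6.16, 4.85, 3.58 and 4.94. Granzyme genes Gzmd and Gzme, at 82.4 and 49.8, rested on 1 cell each, with 98.7% and 99.1% of their UMIs. The integrin gene Itgb7 was lower at 12.3 against 145 CPM, ratio 0.0844 (0.0229–0.217), the chromatin organiser gene Satb1 at 0.149 (0.0178–0.547), the interferon gene Ifit1 at 0.0623 (0.00157–0.352) and type I interferon genes had a median of 0.168 (percentile 0, 6 genes). Some lists of mostly myeloid genes were lower as well, with MHC class II at 0.390 (percentile 0, 7 genes) and T cell attracting chemokines at 0.443 (percentile 0.0550, 5 genes). Others were higher, with costimulatory ligands at 1.84 (percentile 99.975, 4 genes), alternative activation at 1.37 (percentile 95.6, 4 genes) and lysosome and lipid handling at 1.17 (percentile 94.8, 6 genes). A smaller share of myeloid RNA in these deeper cells is thus neither shown nor excluded. Gzma had no UMI in the 20 cells and 111 CPM in the rest, at least 12.1-fold lower at the 3-count floor.

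Mrc1 encodes CD206, a mannose receptor that marks a macrophage subset, and macrophage-like cells were split by its detection at 1000 UMIs per cell. Mrc1 was detected in 284 of 2234 cells (12.7%), and in 77.2% without thinning at a median of 30566 UMIs. CD8 T-like cells, which should lack it, had 0.272% after thinning and 1.91% without, at a median of 6148 UMIs, and melanoma-like cells 0 of 63 after thinning but 12.7% (5.65–23.5) without, at 71218 UMIs. By cluster the share ran from 7.27% (5.08–10.0) in cluster 3 to 41.4% (29.8–53.8) in cluster 15. Alternative activation genes other than Mrc1 had a median of 1.58 (percentile 100, 9 genes), led by Lyve1 at 12.5 against 0.874 CPM, ratio 14.2 (10.2–20.04), with 33.6% of its UMIs in the detected set from 1 cell. Cbr2, a carbonyl reductase gene, was at 40.7 against 9.96 CPM, ratio 4.09 (3.58–4.67), and the folate receptor gene Folr2 at 74.7 against 21.1 CPM, ratio 3.53 (3.21–3.88). The coagulation factor gene F13a1 stood at 128 against 39.2 CPM, ratio 3.25 (3.03–3.50), and the TAM receptor ligand gene Gas6 at 2.65 (2.39–2.94). Among chemokine genes Ccl6 stood at 569.6 against 229 CPM, ratio 2.49 (2.41–2.57), Ccl8 at 2517 against 1197 CPM, ratio 2.10 (2.07–2.14), and Ccl17 at 0.0347 (0.00419–0.126). The lipase gene Lipg was lower at 22.3 against 112 CPM, ratio 0.199 (0.171–0.229), as were the receptor genes Fcrl5 at 0.223 (0.168–0.290) and Cd300e at 50.0 against 120.3 CPM, ratio 0.416 (0.377–0.458). The sets differed in make-up, since cluster 15 gave 29 of the 284 detected and 41 of the 1950 undetected cells, and without clusters 3 and 15 several of these ratios shrank. Folr2 was then at 1.05 (0.882–1.25), Cbr2 at 1.33 (1.05–1.67), F13a1 at 1.56 (1.40–1.73) and Gas6 at 1.68 (1.46–1.92), Lyve1 had 1 UMI in each set, and the log2 median of alternative activation was 0.45 instead of 0.66. Lipg at 0.144 (0.117–0.175), Fcrl5 at 0.227 (0.158–0.316), Cd300e at 0.360 (0.316–0.409) and Ccl8 at 1.80 (1.77–1.83) kept their direction. Make-up still differed among the other clusters. Cluster 1, with Lipg among its 10 leading genes, gave 46 detected and 482 undetected cells. Cluster 2, with Ccl8 and Gas6 among its own, gave 88 and 426. The ratios of these 3 genes may therefore still reflect make-up. T cell genes were higher in the detected cells too, with cytotoxic genes at 1.59 (percentile 98.2, 5 genes), exhaustion genes at 1.26 (percentile 100, 13 genes) and the CD3 genes at 19.6 against 9.06 CPM. This did not hold without clusters 3 and 15. CD3 genes then stood at 5.37 against 10.1 CPM, cytotoxic genes at 0.425 and exhaustion genes at 1.03. Without cells that held a CD3 UMI, 261 against 1812 cells, exhaustion genes were at 1.03 and alternative activation stayed at 1.60.

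MHC class II genes were slightly higher in Mrc1-detected cells, with a median of 1.23 (percentile 100, 9 genes). So were lysosome and lipid genes at 1.27 (percentile 100, 10 genes), led by Fabp5 at 1.70 (1.65–1.75). Interferon gamma response genes were at 1.23 (percentile 100, 8 genes) and receptors at 1.21 (percentile 100, 11 genes). The dissociation stress list moved as much, at 1.20 (percentile 100, 10 genes), so these small shifts cannot be told from handling. Lower medians were found for glycolysis at 0.831 (percentile 0, 11 genes), hypoxia at 0.868 (percentile 0.0300, 10 genes) and cell cycle at 0.878 (percentile 0.0200, 12 genes), with the cyclin gene Ccnb1 at 0.650 (0.582–0.724). Ccnb1 was among the 10 leading genes of cluster 1, which gave 46 of the 284 detected and 482 of the 1950 undetected cells. Its ratio cannot be told apart from this difference in make-up. Type I interferon genes had a median of 1.09 (percentile 98.2, 10 genes), which fell below 1 when the filters, the thinned depth or the averaging of cells was changed, without clusters 3 and 15 and without cells that held a CD3 UMI. The detected and undetected cells had similar depths, with medians of 28774 and 30936 UMIs.

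Spatial barcodes were used to ask which cells and states lay in which marked region. Under the rule that the leading barcode has at least 10 counts and 2 times the next, 76 cells were ZC1, 85 ZC2 and 2207 ZC3, 55.9% of all cells. CD8 T-like cells made up 34.2% (23.7–46.0) of ZC1 cells and 34.1% (24.2–45.2) of ZC2 cells but 4.98% (4.11–5.98) of ZC3 cells. NK-like cells were 15.8% (8.43–25.96) of ZC1 and 0.816% (0.484–1.29) of ZC3 cells. Treg-like cells were 10.5% (4.66–19.7) and 1.54% (1.07–2.15), and cDC2-like cells 17.6% (10.2–27.4) of ZC2 and 2.76% (2.12–3.54) of ZC3 cells. ZC3 was also 58.0% of the spatial UMIs in barcodes with 10 to 100 gene UMIs, about its median of 57.9% in cells, so a lead of ZC3 under this rule does not by itself place a cell. A second assignment, chosen after the data were examined, divided each cell's barcode shares by those in such barcodes, and called 670 cells ZC1, 601 ZC2 and 1081 ZC3. Under it CD8 T-like cells were 15.8% (13.1–18.8) of ZC1 and 6.48% (5.08–8.11) of ZC3 cells. NK-like cells were 4.33% (2.92–6.16) and 1.11% (0.575–1.93), Treg-like cells 4.78% (3.29–6.68) and 1.48% (0.848–2.39), and cDC2-like cells 7.82% (5.80–10.3) of ZC2 and 3.98% (2.89–5.32) of ZC3 cells.

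The macrophage-like clusters differed under both rules, and the rules disagreed on ZC1. Under the first rule ZC3 took 70.1% (65.97–74.0) of cluster 1, 75.0% (70.8–78.9) of cluster 3, 44.4% (37.7–51.3) of cluster 9 and 20% (11.4–31.3) of cluster 15, and ZC1 3.70% (1.61–7.17) of cluster 9 and 0 of the 70 cells of cluster 15. Under the relative assignment ZC1 took 70% (57.9–80.4) of cluster 15 and 30.6% (24.5–37.2) of cluster 9, but 5.68% (3.87–8.01) of cluster 1, 4.91% (3.14–7.28) of cluster 3 and 7.41% (3.89–12.6) of cluster 10. ZC3 took 39.2% (35.02–43.5), 40.8% (36.3–45.4) and 35.8% (28.4–43.7) of clusters 1, 3 and 10, and 2.86% (0.348–9.94) of cluster 15. The CD8 T-like clusters differed too, with 10.5% (6.96–14.98) of cluster 7 and 0 of the 119 cells of cluster 12 in ZC1 under the first rule. The relative assignment gave 38.3% (32.2–44.7) of cluster 7 in ZC1 against 9.24% (4.71–15.9) of cluster 12, and 16.5% (12.1–21.8) against 26.9% (19.2–35.8) in ZC2. NK-like cells of cluster 14 were 38.7% ZC1, Treg-like cells of cluster 13 31.1% ZC1 and cDC2-like cells of cluster 11 32.6% ZC2.

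**Figure D4:**
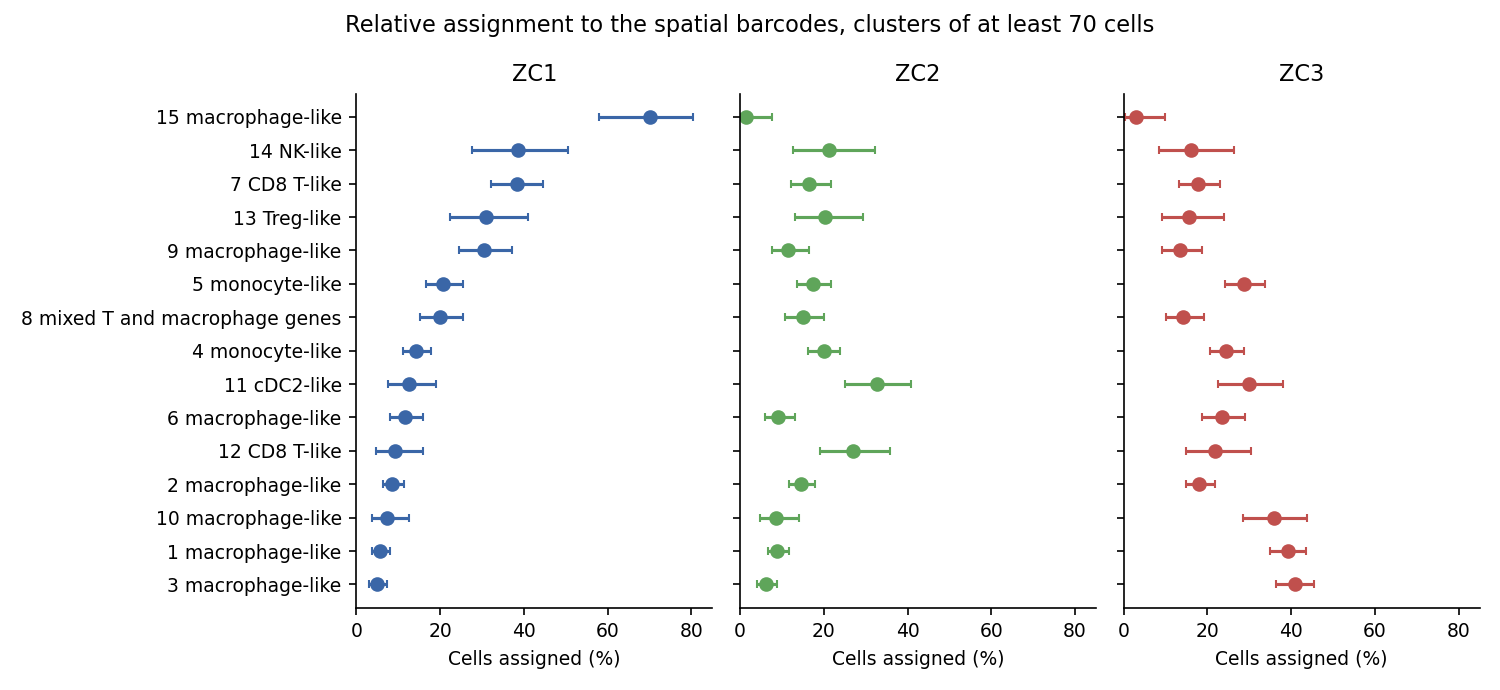
Share of cells (x axis, percent) given to ZC1, ZC2 and ZC3 by the relative assignment in each cluster of at least 70 cells (y axis). Points are the share and lines the exact 95% binomial interval. Cluster 15 stands at 70% ZC1 (0 of its cells by the first rule), and clusters 1 and 3 at 39.2% and 40.8% ZC3.

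CD8 T-like cells of ZC1 were compared with those of ZC3 to ask whether T cell state differed by region. All 26 ZC1 cells belonged to cluster 7, whereas the 110 ZC3 cells were 66 of cluster 7 and 44 of cluster 12. Their median depths were 4526.5 and 6392 UMIs. The ratios below therefore mix region with the difference between these clusters. For cytotoxic, factor, glycolysis and cell cycle genes no value within cluster 7 alone is given, so a difference by region is not shown for them. Progenitor and memory genes were higher in ZC1, with a median of 5.001 (percentile 100, 5 genes). Il7r stood at 234 against 36.9 CPM, ratio 6.35 (3.83–10.3), Tcf7 at 321 against 53.5 CPM, ratio 6.001 (3.93–9.02), the transcription factor gene Klf2 at 269 against 71.6 CPM, ratio 3.76 (2.43–5.68), and Slamf6 at 3.26 (1.85–5.47). Exhaustion genes were lower, at 0.397 (percentile 0.0750, 9 genes), with Tnfrsf9 at 26.03 against 319 CPM, ratio 0.0816 (0.0168–0.240), and Pdcd1 at 0.0839 (0.00211–0.475). Cytotoxic genes were at 0.518 (percentile 0.610, 8 genes), with granzyme B, Gzmb, at 17.4 against 1118 CPM, ratio 0.0155 (0.00188–0.0561), and perforin, Prf1, at 8.68 against 437 CPM, ratio 0.0199 (0.000502–0.111). Factors acting on myeloid cells had a median of 0.325 (percentile 0.0500, 7 genes). Ccl3 stood at 34.7 against 733 CPM, ratio 0.0473 (0.0129–0.122), with 44.6% of the ZC3 UMIs from 1 cell, Xcl1 at 52.1 against 589 CPM, ratio 0.0884 (0.0323–0.193), and Ccl5 at 7192 against 3959 CPM, ratio 1.82 (1.69–1.95). Glycolysis genes had a median of 0.308 (percentile 0, 11 genes), with lactate dehydrogenase Ldha at 286 against 1598 CPM, ratio 0.179 (0.123–0.252). Cell cycle genes had a median of 0.201 (percentile 0, 12 genes), with Stmn1, a microtubule regulator, at 0 and 429 CPM, at least 16.5-fold lower. Outside the lists, the signalling adaptor gene Hcst stood at 885 against 316 CPM, ratio 2.80 (2.24–3.48), the nuclear RNA Malat1 at 2.52 (2.41–2.64), and the quiescence gene Btg1 at 2.21 (1.91–2.54). The dissociation stress list, a sign of handling, moved with these genes, at 2.07 (percentile 100, 9 genes) over ZC3 and 1.63 (percentile 99.5, 5 genes) over ZC2, so a part played by handling stays open. Some lists of mostly myeloid genes were lower in ZC1, with MHC class II at 0.524 (percentile 2.60, 6 genes) and T cell attracting chemokines at 0.306 (percentile 0.575, 3 genes). Myeloid receptors, at 1.36 (percentile 84.9, 3 genes), and checkpoint ligands, at 1.20 (percentile 72.8, 3 genes), were not. Cd4 was found in 26.9% of the ZC1 and 25.5% of the ZC3 cells, so CD4 T cells among both are not excluded.

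Under the relative assignment, with 106 ZC1 and 70 ZC3 cells, the median log2 ratio of exhaustion genes was -0.83 instead of -1.33, and that of factors acting on myeloid cells turned to 0.23 from -1.62. Within cluster 7 alone, 95 against 44 cells, exhaustion genes had a median log2 ratio of -0.59 and progenitor genes 0.89 instead of 2.32. Without cells that held a Cd4 UMI, 86 against 53 under the relative assignment, exhaustion genes were at -0.87 and progenitor genes at 2.27; the first rule left 19 ZC1 cells, too few to compare. As a mean of per-cell CPM the progenitor value was 1.09. Type I interferon genes had a median of 1.87 (percentile 97.8, 4 genes) and changed sign in 3 of the alternatives, so no direction is given for them. In the 29 ZC2 cells, 20 of cluster 7 and 9 of cluster 12, cytotoxic genes had a median of 0.378 (percentile 0, 8 genes) over ZC3. Gzmb was at 132 against 1118 CPM, ratio 0.118 (0.0830–0.164), Prf1 at 0.139 (0.0806–0.225), and the interferon-induced chemokine gene Cxcl10, mostly a myeloid gene, at 0.0892 (0.0241–0.232). Some lists of myeloid genes and the list of handling were lower in ZC2 too, with T cell attracting chemokines at 0.177 (percentile 0.00500, 3 genes), MHC class II at 0.452 (percentile 0, 6 genes) and dissociation stress at 0.599 (percentile 1.22, 10 genes). Myeloid receptors were not, at 1.20 (percentile 90.7, 5 genes). Exhaustion genes had a median of 0.943 (percentile 40.1, 9 genes) there, Cxcr6 stood at 562 against 351 CPM, ratio 1.60 (1.33–1.92), and progenitor genes had a median of 1.37 (percentile 97.7, 6 genes) with members on both sides, from 0.450 (0.1998–0.889) for Klf2 to 3.23 (1.57–6.46) for Lef1, with Il7r at 2.52 (1.51–4.12). ZC1 over ZC2 gave 3.23 (percentile 100, 4 genes) for progenitor genes, with Klf2 at 269 against 32.2 CPM, ratio 8.35 (3.88–19.95). Exhaustion genes were at 0.356 (percentile 0.0100, 6 genes), with Lag3, an inhibitory receptor gene, at 52.1 against 393 CPM, ratio 0.132 (0.0475–0.297).

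**Figure D5:**
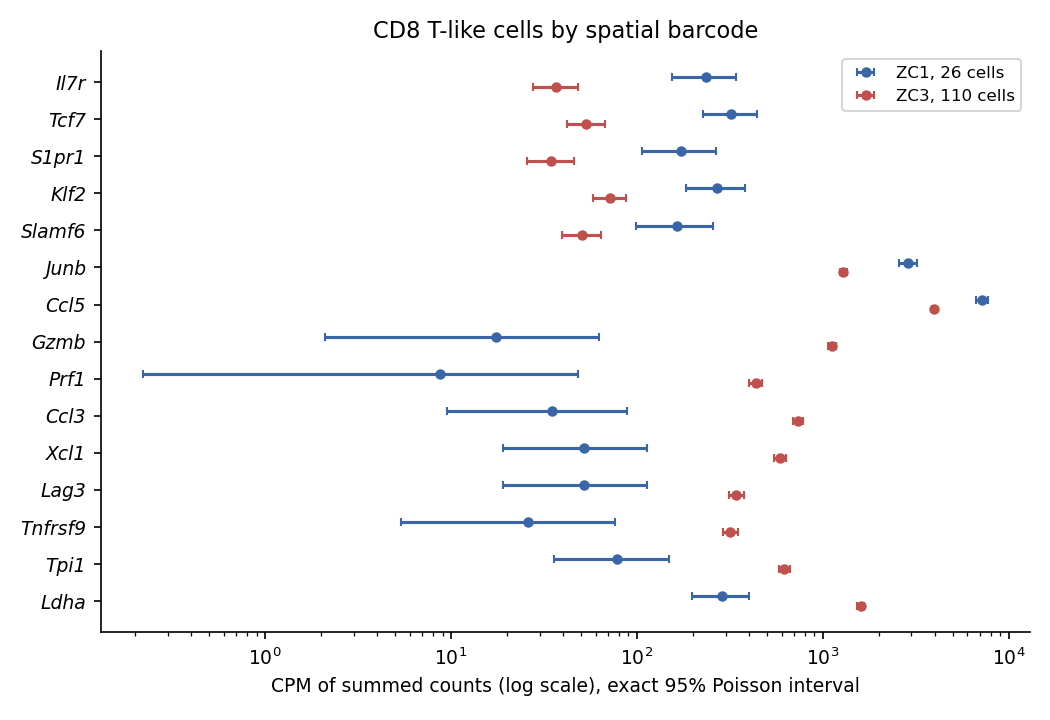
CPM of summed counts (x axis, log scale) of genes (y axis) in the 26 ZC1 and 110 ZC3 CD8 T-like cells, with points for the level and lines for exact 95% Poisson intervals. Tcf7 stands at 321 CPM in ZC1 and 53.5 in ZC3, and Gzmb at 17.4 and 1118 CPM.

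Monocyte-like cells were compared between the same regions under the relative assignment, 137 ZC1 and 210 ZC3 cells with medians of 12630 and 12333 UMIs; this comparison was added after the data were examined. Cell cycle genes shifted most, at 0.378 (percentile 0, 10 genes). Type I interferon genes were lower in ZC1, with a median of 0.464 (percentile 0, 10 genes), Ifit3 at 40.5 against 190.1 CPM, ratio 0.213 (0.166–0.270), and Isg15 at 286 against 543 CPM, ratio 0.528 (0.478–0.581). Cxcl10 stood at 351 against 1209 CPM, ratio 0.291 (0.268–0.316). Inflammatory genes had a median of 1.76 (percentile 100, 5 genes), with the neutrophil chemokine gene Cxcl2 at 509 against 258 CPM, ratio 1.97 (1.79–2.16), and Ptgs2 at 112 against 58.0 CPM, ratio 1.94 (1.58–2.37). Ccl2 was lower at 351 against 1006 CPM, ratio 0.349 (0.321–0.380). Lysozyme Lyz1 stood at 236 against 21.1 CPM, ratio 11.2 (8.65–14.7), the tetraspanin gene Cd81 at 125 against 35.6 CPM, ratio 3.50 (2.79–4.42). The matrix glycoprotein gene Thbs1 was at 2.74 (2.33–3.23), the angiogenic factor gene Vegfa at 57.7 against 24.9 CPM, ratio 2.32 (1.72–3.13), and Ifngr1 at 349 against 179 CPM, ratio 1.95 (1.74–2.18). MHC class II genes had a median of 1.24 (percentile 100, 8 genes) and hypoxia genes 0.659 (percentile 0, 9 genes). Vegfa, a member of the hypoxia list, went the other way, while 5 of the 9 genes were at least 1.5-fold lower. The heat shock gene Hspa1a stood at 87.3 against 789 CPM, ratio 0.111 (0.0941–0.129). Within cluster 4, 64 against 109 cells, the medians were 0.494 for type I interferon, 1.47 for inflammatory and 1.31 for MHC class II genes, and within cluster 5, 73 against 101 cells, 0.382, 1.59 and 1.95. The dissociation stress list was at 1.05 (percentile 88.9, 10 genes) over both clusters, but at 1.40 in cluster 4 and 0.608 in cluster 5. A part played by handling within each cluster stays open. The 150 ZC2 cells had medians over ZC3 of 0.628 (percentile 0, 9 genes) for hypoxia and 0.799 (percentile 0.0100, 10 genes) for type I interferon genes, but the dissociation stress list shifted by more than the latter, to 0.697 (percentile 0, 10 genes). Spp1 was at 0.363 (0.329–0.401), the monocyte chemokine gene Ccl7 at 174 against 737 CPM, ratio 0.236 (0.212–0.262), and Ccl5 at 369 against 175 CPM, ratio 2.11 (1.90–2.36).

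Macrophage-like clusters 1, 2, 3, 6 and 9 had at least 20 ZC1 and 20 ZC3 cells under the relative assignment and were compared, also after the data were examined; genes were read in cluster 2, the first compared, with 44 and 93 cells. Inflammatory genes had a median of 1.54 (percentile 100, 5 genes), with Cxcl2 at 263 against 117 CPM, ratio 2.25 (1.91–2.64), and Cxcl1 at 2.94 (1.58–5.53). The arginase gene Arg1 stood at 161 against 66.6 CPM, ratio 2.42 (1.96–2.98). The monocyte receptor gene Ccr2 was at 260.3 against 122 CPM, ratio 2.13 (1.82–2.50), and S100a4, a calcium-binding protein gene, at 153 against 45.8 CPM, ratio 3.34 (2.64–4.23), with 45.1% of its ZC1 UMIs from 1 cell. Type I interferon genes had a median of 0.558 (percentile 0.0650, 5 genes), and hypoxia genes 0.750 (percentile 0.0600, 8 genes). Spp1 stood at 51.4 against 117 CPM, ratio 0.438 (0.326–0.581), Gbp2 at 117 against 215 CPM, ratio 0.544 (0.447–0.658), and Ccl8 at 1660.2 against 2675 CPM, ratio 0.621 (0.590–0.653). The other clusters did not all share these directions. Type I interferon genes had medians of 0.325, 0.687 and 0.886 in clusters 1, 3 and 6 but 2.25 in cluster 9, with 66 ZC1 and 29 ZC3 cells. Hypoxia genes were at 0.624, 0.772 and 0.642 in clusters 1, 3 and 9 and 1.14 in cluster 6, inflammatory genes at 1.497, 1.03, 1.18 and 1.20 in clusters 1, 3, 6 and 9, and MHC class II genes between 1.09 in cluster 2 and 1.35 in cluster 1. The dissociation stress list was at 1.83 in cluster 9.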

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

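The tests of CD3 counts against free RNA, of Y-linked genes with and without thinning, of Xist with dsredexpress1, of dsredexpress1 in NK-like and Treg-like cells, of barcodes with 20 C1q UMIs, of barcodes with B cell genes, and of free spatial barcodes were chosen only after the result was seen. The reference held fluorescent protein sequences that no comparison used: dsredexpress1 had 376 UMIs over all barcodes and mVenus 18, both above the limit that a count of 0 allows. Of the dsredexpress1 UMIs 271 lay in CD8 T-like cells, 62 in the mixed cluster and 10 in melanoma-like cells. It was found in 10.9% (7.90–14.5) of CD8 T-like cells, at a median of 6148 UMIs. In melanoma-like cells it was found in 8 of 63 (12.7%, 5.65–23.5), at a median of 71218 UMIs, and 0 of these cells had Xist. Of the 15 cells kept with mVenus 13 were macrophage-like, with 13 UMIs, and this class held 65.7% of the UMIs of all cells kept. These are too few to judge a preference. What either sequence reports is not stated, and a reporter of Mrc1, which could change what the Mrc1 split means, is not excluded.

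Cluster 8 held 246 barcodes with both T cell and macrophage genes, and 93.9% of them had at least 3 CD3 UMIs. Its median Scrublet score was 0.141, against 0.00904 to 0.0819 in the other clusters, below the automatic threshold of 0.518. The test of free RNA set a median of 21 CD3 UMIs per barcode against 0.0250 in 100 UMIs of free RNA. The rule for a mixed cluster made that outcome near certain. Free RNA is argued against because 21 CD3 UMIs would take 84060 UMIs of free RNA, and the barcodes held a median of 34643 UMIs. An earlier test, the CD3 level over that of the highest macrophage-like cluster (6.66), left this undecided. A single cell type with both programmes could be tested in only 10 of the 246 barcodes. It is argued against in those 10, which held Xist and dsredexpress1. Of these 100% also had a Y-linked UMI (lower bound 69.2%) at a median of 49386 UMIs, and 9 of 10 (90%, 55.5–99.7) when thinned to 18048. Of such CD8 T-like cells, whose median was 18048, 13.5% (4.54–28.8) had one. A preference for the T cells of cluster 12 was tested on Xcl1 alone. The mixed cluster held 9.74 (9.02–10.5) Xcl1 UMIs per 100 CD3 UMIs, against 21.3 (20.6–22.1) in both CD8 T-like clusters, which goes against it. Of other genes higher in cluster 12, Lag3, Pdcd1 and Gzmb were lower too. Tnfrsf9 was higher, at 9.30 (8.59–10.06) against 7.80 (7.34–8.27), and Rgs16 differed little. Foxp3, at 2.45 per 100 CD3 UMIs, leaves room for T cells of other classes, so this question stays open. Random capture of a pair of cells in 1 droplet cannot be told apart from cells held together by the test set first, since macrophage levels of C1q were found in 23.6% (15.2–33.8) of barcodes with NK genes and 36.0% (32.6–39.6) of those with CD3 genes, whose intervals overlap, while barcodes with B cell genes, with 13.04% (4.94–26.3) of 46, lay apart from the latter. With at least 20 C1q UMIs as well the shares were 19.1% (11.5–28.8) and 33.4% (30.01–36.9), with intervals apart, so a T cell and a macrophage held together in 1 droplet may add to chance capture, a hypothesis for which no biological explanation was tested.

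Xist, which female cells transcribe, and dsredexpress1 met in the same cells of CD8 T-like cluster 12: 36 of its 38 dsredexpress1 cells had Xist (94.7%, 82.3–99.4), against 31.9% of all its cells. Free RNA is argued against by 0% of 178 NK-like and Treg-like cells with a dsredexpress1 UMI at 1000 UMIs, against 5.88% (2.40–11.7) of cluster 12. Doublets of a female and a male cell are argued against by a Y-linked UMI in 13.5% (4.54–28.8) of CD8 T-like cells with both, against 94.9% (87.5–98.6) of the cluster 12 cells with neither, at median depths of 18048 and 15079 UMIs. These cells may come from a female source that carries dsredexpress1 beside a male one, a hypothesis for which the labels name no sex, donor or transfer, so no biological explanation was tested.

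Macrophage-like cluster 15 was given to ZC1 for 70% of its cells by the relative assignment, chosen later, but for 0 of 70 by the first rule, which gave 20% to ZC3, and its median shares were 31.0% ZC1 and 44.8% ZC3. For free spatial barcodes, this ZC1 share lay above the 90th percentile of melanoma-like cells (25.7%), at median depths of 3956.5 and 216 spatial UMIs. The cluster was picked for its lead of ZC1 relative to free barcodes, which made a high ZC1 share likely beforehand. This comparison therefore decides nothing about free spatial barcodes. For counting noise, 68.9% (55.7–80.1) of its 61 cells with at least 1552.5 spatial UMIs were ZC1. With 61 of 70 cells above that depth this share could hardly differ from the 70% of the whole cluster, so it is no separate test. The depth of these cells, rather than that share, goes against noise at few spatial UMIs. A position of these cells nearer the ZC1 region may explain the pattern, but it rests on the relative assignment alone, the region is not stated and no biological explanation was tested.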

How the results depend on the processing

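The tests with a Scrublet limit of 0.12, the relative assignment, cluster 7 alone, the mean per cell in the CD8 T-like comparisons, the omission of cluster 4, of clusters 3 and 15, and of cells with CD3 or Cd4 UMIs were chosen only after the result was seen. Over 73 results, 564 alternatives gave 317 values close to the first, 233 moved and 14 reversed, and the cause was not tested. A change of sign was counted as reversed only for lists outside the middle 95% of random lists, and 24 further changes of sign fell on other lists. No paired analysis was possible because there was 1 library. Median log2 ratios are given unless a percent is shown.

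With at least 500 UMIs and 250 genes, macrophage-like cells made up 48.9% (first 52.7%), monocyte-like 21.4% (18.8%) and CD8 T-like 6.09% (8.66%). In macrophage-like against monocyte-like cells MHC class II was -1.03 (-0.98) and type I interferon -1.02 (-1.48), the cytotoxic list of the Pdcd1 and Havcr2 split reversed to -0.74 (1.05), Mrc1 alternative activation was 0.36 (0.66) and Mrc1 type I interferon reversed to -0.0695 (0.12). With at least 2000 UMIs and 1000 genes the shares were 50.9% and 23.1% for macrophage-like and monocyte-like cells, type I interferon -1.06, Mrc1 alternative activation 0.40 and Mrc1 type I interferon -0.22, reversed. A mitochondrial limit of 5% gave 48.6%, 24.6% and 7.32% for the same 3 classes, and 20% gave 17.6% monocyte-like cells. These filters kept 4300, 4165, 3607 and 4325 cells.

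Leiden resolution 0.5 gave 21.2% monocyte-like cells and type I interferon -1.30. Resolution 2 gave 47.2% macrophage-like, 16.9% monocyte-like and 6.49% CD8 T-like cells, MHC class II -0.91 and type I interferon -1.62. State-list genes in clustering gave 51.1%, 21.6% and 6.49%, with -1.04 and -1.06. Removing Scrublet scores over 0.12 gave 24.8% monocyte-like cells. Without cluster 4, MHC class II reversed to 0.51 and type I interferon was -1.80. Without macrophage-like clusters 3 and 15 they were -0.86 and -1.35, Mrc1 alternative activation was 0.45, and Mrc1 type I interferon reversed to -0.14 and Mrc1 inflammatory activation to -0.0387 (0.25). Without cells with a CD3 UMI, Mrc1 alternative activation was 0.68 and Mrc1 type I interferon reversed to -0.0656.

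The mean of per-cell CPM gave MHC class II -0.77, exhaustion in the Pdcd1 and Havcr2 split 1.82 (1.28), Mrc1 alternative activation 0.57, Mrc1 type I interferon -0.16, reversed, factors acting on myeloid cells in cluster 12 2.90 (2.67), ZC1 progenitor genes 1.09 (2.32) and ZC1 type I interferon -0.0323, reversed from 0.90. Thinning to 2000 UMIs gave exhaustion 0.77, Mrc1 alternative activation 0.40 and Mrc1 type I interferon -0.18, reversed; no thinning gave 0.98 and -0.52, the latter reversed. Pdcd1 alone gave exhaustion 0.55.

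The relative assignment gave macrophage-like, clusters 3 and 15 included, 38.2% of ZC1 (14.5%) and 59.7% of ZC3 (62.1%), CD8 T-like 15.8% (34.2%) and 6.48% (4.98%), ZC1 over ZC3 exhaustion -0.83 (-1.33), factors 0.23, reversed from -1.62, and type I interferon -0.14, reversed. In cluster 7 alone these cells gave exhaustion -0.59, progenitor 0.89 and type I interferon -1.22, reversed. Without cells with a Cd4 UMI the relative assignment gave exhaustion -0.87; the first rule left 19 ZC1 cells and no value. A factor of 1.5 gave exhaustion -1.09 and progenitor 1.76. A factor of 5 gave 55.5% macrophage-like and 8.08% CD8 T-like cells in ZC3, but 0 CD8 T-like cells in ZC1, so no list value. Keeping doublets changed nothing because 0 were called, which makes that alternative void.

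In macrophage-like over monocyte-like cells the medians of alternative activation (0.21), inflammatory activation (0.51) and hypoxia (0.20) also changed sign, to -0.77 and -1.47 for the first pair with at least 500 UMIs and to -0.48 for hypoxia without cluster 4. With 4000 variable genes, seed 1 and free RNA subtracted, no value given above moved past the limits used for it. Depth limits the Pdcd1 and Havcr2 split, which held 2 cells.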

Other observations

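The partner genes in the mixed cluster and the state of cells with Xist and dsredexpress1 were looked at only after the result was seen, so these tests describe and decide nothing. Per 100 CD3 UMIs the mixed cluster held 3.94 Tcf7, 5.55 Il7r, 9.30 Tnfrsf9, 7.34 Lag3 and 2.45 Foxp3 UMIs, against 1.89 Tcf7, 1.85 Il7r, 7.80 Tnfrsf9 and 8.89 Lag3 in the CD8 T-like clusters together. Il7r was also at 17.98 CPM in macrophage-like cells, against 39.1 CPM in the mixed cluster, so macrophages may hold part of its UMIs. Xcl1 stood at 30.4 UMIs per 100 CD3 UMIs in cluster 12 and 4.67 in cluster 7.

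The macrophage-like clusters differed in state genes: the glucose transporter gene Slc2a1 stood at 729.5 CPM and the nitric oxide synthase gene Nos2 at 51.9 CPM in cluster 6, the interferon gene Isg15 at 633 CPM and Cxcl9 at 3900.3 CPM in cluster 10. Retnla, at 545 CPM in free RNA, stood at 645 CPM in cluster 9 and 781 CPM in cluster 15, where Lyve1 was at 106 CPM, Folr2 at 447 CPM, Mrc1 at 454 CPM and Ccl8 at 4088 CPM. MHC class II gene H2-Aa stood at 9061 CPM in monocyte-like cluster 4 and 2452 CPM in cluster 5, and from 1725 CPM in cluster 3 to 7897 CPM in cluster 9 among macrophage-like clusters.

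Within CD8 T-like cluster 12, the 36 cells with Xist and dsredexpress1 were set over the 79 cells with neither. Median ratios were 0.423 for cytotoxic, 0.758 for exhaustion and 2.16 for 3 progenitor genes. Some lists of myeloid genes rose, with MHC class II at 2.35, T cell attracting chemokines at 3.81 and alternative activation at 2.07. Others fell, with myeloid receptors at 0.794, lysosome and lipid handling at 0.799 and checkpoint ligands at 0.678. RNA of myeloid cells in these barcodes is therefore not excluded. Without cells that had Xist or dsredexpress1, cluster 12 over cluster 7 (79 against 246 cells) had medians of 2.93 for exhaustion and 4.92 for factors acting on myeloid cells, and without Cd4 cells (99 against 191) 2.43 and 4.93. Alternative activation, at 5.12 over all cells (4 genes), was at 1.86 (3 genes) without cells that had Xist or dsredexpress1. Macrophage-like cells had a Y-linked UMI in 93.8% and Xist in 0.313% of cells.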
